A study of Rattus norvegicus with 6 samples.

How the data were processed

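RNA was sequenced from rat trophoblast stem cells with a control shRNA (3 libraries) or an shRNA against Suv39h2 (3 libraries), on day 8 of differentiation. Per the labels' protocols, the libraries were made with TruSeq kits and sequenced as paired 100-bp reads on a HiSeq 2000. Per the labels' protocols, the authors mapped the reads to the rat genome Rnor_5.0 with Ensembl release 78 annotation in CLC Genomics Workbench 12.0. The authors expressed abundance in RPKM (mapped reads scaled by exon length and by library total), which per the file headers is given for each library and as a mean for each group. The deposited false discovery rate is a p-value adjusted by the authors. Neither the test behind it nor the number of features tested is stated. The deposited fold change is a signed linear ratio of the group means (another unit), with falls written as the negative of control over knockdown. It was checked to equal the ratio of the deposited means within 1e-9. The protocol text also names a comparison of normal with high glucose, a human stem cell medium and extravillous trophoblast differentiation, and the glucose comparison matches no sample here.

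The deposited workbook has 4 sheets with 570 features in all, 328 lower, 242 higher and 38 selected candidates. The sheets of lower features, higher features and selected candidates were each checked against the sheet of all features, and 0 RPKM values differed. Only features past a false discovery rate of 0.05 are present. The number of features tested is unknown, and no enrichment over the genome was computed. The sheets give no counts or library totals, so the depth per library is unknown, and no counting interval or detection floor is given. A feature is a line of the table, a gene symbol with a running number. Whether it stands for a gene or a transcript is not stated, and 547 distinct names cover the 570 features. Gene symbols of 537 features were matched to current rat gene names, and coordinates are those of the deposit.

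Groups followed the sample labels. In 3 of the 4 sheets the control columns are named S4, S5 and S6, and these names are used for control libraries. The sheet of lower features numbers its columns as the labels do, and over its 328 features S4, S5 and S6 held exactly the values of control samples 1, 2 and 3. These numbers were used for a fit with replicate number as a block.

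These choices were fixed before the data were examined: the groups, the main test, 21 gene lists, the rule for named genes and most alternatives. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1) without a filter, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the 570 features. Each of the 12 lists with at least 5 features in the table was tested with Fisher's exact test, two-sided, of its higher and lower features against all other features, with Benjamini-Hochberg adjustment over the 12 lists. Features are not independent replicates, so this test describes the split within the table. The count adjusted over the list alone applies the adjustment to the members of a list only. All 570 features had an unadjusted limma p below 0.05, so every list passes in full and this count adds no evidence. The level of Suv39h2 was also compared with an exact permutation test. The genes named are Suv39h2 and Suv39h1, the 12 largest rises and 12 largest falls among features with an official symbol and at least 1 RPKM in the higher group, the up to 4 largest changes of each list, and the 5 largest rises and falls of the selected candidates. Krt8, Krt18, Hand1, Gjb3, Plau, Cdh1, Top2a, Mki67, Mcm3, Cldn6, Trim28, Peg3, Ldha, Aldoa, Hif1a, Prl3d1, Prl3d2, Itgb2, Was, Spn, Rps18, Rpl10l, Eef1a1 and the main Rps20 feature were named in addition, after their values were seen, as were genes of the 5 lists described only in the closing section.

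The alternatives were a pseudocount of 0.1, a minimum mean of 1 RPKM, quantile normalization, limma without a trend, leaving out each library in turn, the replicate block, a deposited false discovery rate of 0.01, a fold of at least 2, a maximum group mean of at least 1 and, for the lists, official symbols only. Added after the data were seen were a fold of at least 1.5, a single feature per gene, and scaling each library to the same median of the ribosomal protein list. Ribosomal proteins by name, a set of 43 features, were also chosen after the data were seen. Tests on counts were not run, because the sheets hold no counts. The limma code was tested on simulated data of 570 features with 200 changed and recovered 79% of changes of 0.25 and 95% of changes of 0.5 on the log2 scale, with 5.43% of its calls false and 0 of wrong sign. The simulated features were not selected beforehand, unlike the deposited ones, so these rates check the code and do not describe the calls made here. Summaries used Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.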

Results

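Rat trophoblast stem cells, the cells that give rise to the trophoblast of the rat placenta, were transduced for 24 h with lentivirus carrying a control shRNA or an shRNA against Suv39h2. Suv39h2 encodes a histone methyltransferase that methylates H3K9, a mark of silent chromatin. The cells were selected with puromycin for 2 days and then differentiated, and RNA was collected on day 8 of differentiation. RNA sequencing gave 3 control libraries and 3 knockdown libraries. The comparison of the 2 groups asks how a reduced level of Suv39h2 alters the fate of these cells. The deposited table holds 570 features, all of which had passed the authors' false discovery rate of 0.05, with 547 distinct names. Features that did not pass are absent, so nothing can be said about genes that stayed level. The table gives no read counts or library totals, and the depth behind each value is therefore unknown. Abundance is given in RPKM as mean ± SD over the 3 libraries of a group, and folds are ratios of these means.

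The targeted transcript was lower in the knockdown cells. Suv39h2, on chromosome 17 at 80406939 to 80425965 of Rnor_5.0, stood at 14.7 ± 0.714 RPKM in control libraries and at 4.94 ± 0.379 RPKM in knockdown libraries (n = 3 each). The fall was 2.97-fold and left 33.7% of the control level. The control libraries were at 15.4, 13.9 and 14.7 RPKM, and the knockdown libraries were at 4.89, 4.59 and 5.34 RPKM. The gap between the groups was larger than the spread within either of them (limma adjusted p = 1.59e-06). An exact two-sided permutation test gave p = 0.1, the smallest p that 3 libraries against 3 can give. Suv39h1, which encodes the related methyltransferase, had 0 features in the table.

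In knockdown cells, listed features of the prolactin family, of giant and invasive trophoblast and of steroid synthesis were mostly higher, and listed features of the cell cycle were lower. Of the 570 features, 242 were higher and 328 were lower in the knockdown. The median fold was 1.97 among the higher features and 1.49 among the lower ones, and 116 higher and 68 lower features changed at least 2-fold. The median control level was 38.7 RPKM for the higher features and 125.9 RPKM for the lower ones. The smallest fold in the table was 1.81 under 20 RPKM in controls and 1.08 over 500 RPKM. The fold sizes therefore do not show that rises were stronger than falls. The median coefficient of variation between libraries of a group was 4.01% in controls and 3.62% in knockdowns. All 570 features also passed limma, with a highest adjusted p of 0.0456, but these features had been selected on the same libraries, so the refit describes their spread and is not a second test. The labels do not say that the libraries of a group came from separate cultures, so each limma p weighs a change only against the spread between these samples.

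**Figure D1:**
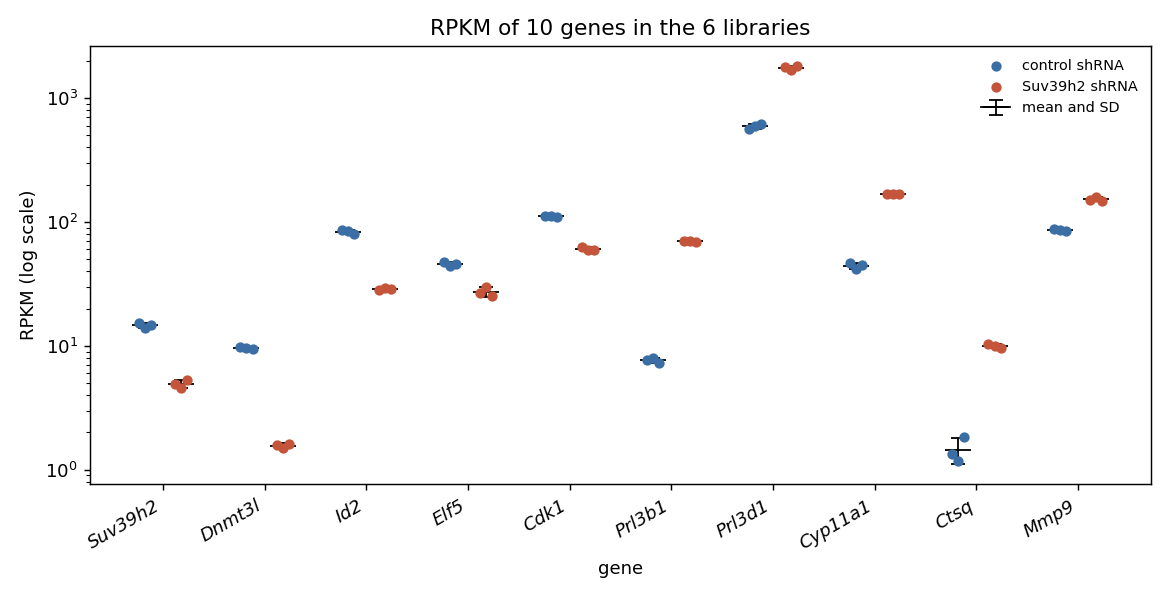
RPKM on a log scale of 10 genes in the 3 control libraries and the 3 Suv39h2 knockdown libraries, with each point a library and black bars for the mean and SD. Suv39h2 fell from 14.7 to 4.94 RPKM, Prl3b1 rose from 7.65 to 69.7 RPKM, and the libraries of the 2 groups did not overlap for any gene drawn. The same held for 569 of the 570 features, which had been selected on these same libraries.

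The largest rise belonged to a placental hormone. Prl3b1, which encodes placental lactogen II of trophoblast giant cells, rose 9.11-fold from 7.65 ± 0.354 to 69.7 ± 0.834 RPKM (log2 change 3.03, adjusted p = 8.73e-09). All 9 features of the prolactin family in the table, from 8 of 23 listed genes, were higher, by 2.18-fold to 9.11-fold. Prl5a1 rose 6.58-fold from 2.29 ± 0.636 to 15.1 ± 1.64 RPKM, and Prl2a1 rose 5.01-fold from 99.7 ± 3.21 to 499 ± 12.4 RPKM. The 2 features of Prl8a9 rose 5.81-fold and 5.66-fold. The most abundant members, Prl3d2 and Prl3d1, which encode forms of placental lactogen I, were 2.44-fold and 2.96-fold higher. Their coding sequences are close to one another, so the division of reads between them is uncertain. The 9 features lay on chromosome 17 between 40184557 and 44721873. Among all other features 41.5% were higher (Fisher's exact test, two-sided, adjusted p = 0.00123 over the 12 lists tested). With only features of at least 2-fold, 61.1% of the others were higher, and the adjusted p of this test was 0.0458. Over its alternatives the adjusted p ranged from 0.000689 to 0.0458. All 9 also passed when adjusted over the list alone.

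Genes of trophoblast giant cells and invasive trophoblast in the table, 23 of 50 listed, mostly rose. Of their 24 features, 23 were higher and 1 was lower (Fisher's exact adjusted p = 2.62e-07, in a range of 2.12e-07 to 0.00164 over its alternatives). All 24 passed when adjusted over the list alone. Ctsq, a placenta-specific cathepsin, rose 6.85-fold from 1.45 ± 0.348 to 9.96 ± 0.39 RPKM, and Cts8, of the same family, rose 3.32-fold. Mmp12, a macrophage-type elastase, rose 4.61-fold from 2.15 ± 0.175 to 9.89 ± 0.771 RPKM. Ceacam9, a placental adhesion protein, rose 4.24-fold from 91.1 ± 4.67 to 386 ± 11.3 RPKM. Hand1, a transcription factor required for giant cell formation, was 2.22-fold higher. The keratins Krt8 and Krt18, at 959 and 1035 RPKM in controls, were 1.34-fold and 1.37-fold higher. The exception was Gjb3, a gap junction protein, which was 1.68-fold lower. Cathepsins of the placental cluster, carcinoembryonic-antigen-like genes and serpins of the Serpinb9 group have near copies in the rat genome, so the share of reads between copies is uncertain.

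Extracellular matrix and adhesion features were mostly higher, 9 of 10 (Fisher's exact adjusted p = 0.00617), and all 10 passed when adjusted over the list alone. Mmp9, Serpine1, Cdh5, Plau and Mmp12, all higher, are also in the giant and invasive trophoblast list. The results of these lists therefore overlap and are not independent. The 2 features of FN1, which encodes fibronectin, rose 4.78-fold (8.82 ± 1.5 to 42.1 ± 0.642 RPKM) and 4.14-fold (12.9 ± 1.97 to 53.6 ± 0.513 RPKM). The protease inhibitor Serpinb9b, listed under its provisional name, rose 3.23-fold, and the urokinase gene Plau was 2.28-fold higher. Cdh1, which encodes the epithelial adhesion protein E-cadherin, was 2.79-fold lower. With only features of at least 2-fold in the table, the adjusted p of this list was 0.328, within a range of 0.00588 to 0.328 over its alternatives.

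The steroid hormone synthesis list had 5 features in the table, all higher (Fisher's exact adjusted p = 0.0269), and all 5 passed when adjusted over the list alone. Cyp11a1, which makes pregnenolone from cholesterol, rose 3.76-fold from 44.3 ± 2.28 to 167 ± 0.071 RPKM. Cyp17a1, which leads from progestins to androgens, rose 2.53-fold, and Hsd17b2, which inactivates estradiol and testosterone, rose 2.06-fold. The 2 features of Hsd3b1 rose 2.40-fold and 1.82-fold. When libraries were scaled to equal ribosomal protein RNA, all 5 stayed higher while the adjusted p of the split was 0.0543, within a range of 0.0173 to 0.0543 over its alternatives.

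Other large rises were Fndc3c1 (6.05-fold, 3 ± 0.176 to 18.1 ± 0.76 RPKM), the protease inhibitor Serpinb9d (5.25-fold), the small GTPase Rasd1 (4.48-fold) and the cathepsin Ctsj (4.16-fold).

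The members of the cell cycle and mitosis list in the table were all lower, while most of its 84 genes were absent. All 27 of its features in the table, from 26 genes, fell by 1.30-fold to 2.45-fold (Fisher's exact adjusted p = 1.43e-06), and all 27 passed when adjusted over the list alone. Kif23, a kinesin of cytokinesis, was 2.45-fold lower (35.1 ± 0.806 to 14.3 ± 1.39 RPKM). Cdc20, an activator of the anaphase-promoting complex, was 2.23-fold lower (63.1 ± 2.07 to 28.2 ± 1.34 RPKM). Prc1, which bundles the central spindle, was 2.22-fold lower and the mitotic kinase Aurkb was 2.04-fold lower. The replication and proliferation genes Top2a, Mki67 and Mcm3 were 1.91-fold, 1.73-fold and 1.64-fold lower.

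The members of the trophoblast stem-state list in the table, 5 of 32 genes, were all lower. Id2 and Id1, inhibitors of basic helix-loop-helix factors, fell from 83.6 ± 2.54 to 28.7 ± 0.496 RPKM (2.91-fold) and from 75.6 ± 3.16 to 35.2 ± 2.38 RPKM (2.15-fold). Satb1, a chromatin organiser, was 1.89-fold lower, the stem-state transcription factor Elf5 was 1.68-fold lower and the claudin Cldn6 was 1.46-fold lower. With 5 features in the list, the split against the rest of the table did not pass (0 higher and 5 lower, Fisher's exact adjusted p = 0.097). Each of the 5 passed on its own and when adjusted over the list alone. Every feature in the table did so, and this does not offset the result of the split.

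Of the 38 listed genes of the H3K9 and DNA methylation machinery, 5 were in the table and all 5 were lower. They include Suv39h2, which the shRNA was meant to lower. The split did not pass (Fisher's exact adjusted p = 0.097, all 5 past when adjusted over the list alone). Dnmt3l, a catalytically inactive partner of the de novo DNA methyltransferases, had the second-largest fall in the table, 6.15-fold from 9.64 ± 0.206 to 1.57 ± 0.0691 RPKM. Dnmt3b, a de novo DNA methyltransferase, was 1.98-fold lower. Uhrf1, which directs maintenance methylation, was 1.82-fold lower and the corepressor Trim28 was 1.45-fold lower. Tex15, a gene of germ cell development and the sole member of the germline list in the table, was 2.36-fold lower.

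**Figure D2:**
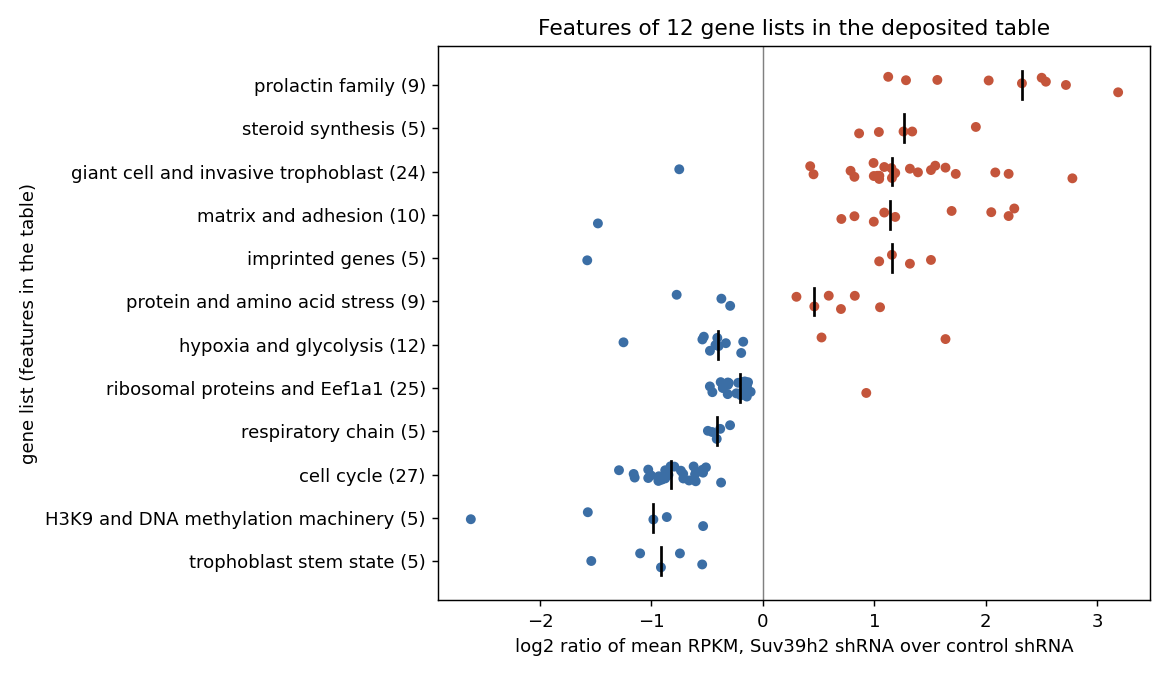
Log2 ratio of mean RPKM, knockdown over control, for each feature of the 12 lists with at least 5 features in the table, with a point per feature and a black bar at each list's median. All 9 prolactin family features lie above 0 and all 27 cell cycle features below 0, while 24 of the 25 features of the list of ribosomal proteins and Eef1a1 lie just below 0, of which 12 cross it when libraries are scaled to equal ribosomal protein RNA. That scaling removes the median fall of this list by construction.

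Imprinted genes went both ways. PHLDA2, a maternally expressed growth restrainer of the placenta, was 2.98-fold lower (137 ± 9.94 to 46 ± 4.3 RPKM). Its neighbour Cdkn1c, a cyclin-dependent kinase inhibitor that is also maternally expressed, was higher in both of its features (12.4 ± 2.7 to 35.2 ± 3.17 RPKM and 57.6 ± 2.66 to 144 ± 2.82 RPKM). The paternally expressed Igf2 and Peg3 were 2.23-fold and 2.06-fold higher. The split of 4 higher and 1 lower did not differ from the rest of the table by the test (Fisher's exact adjusted p = 0.179, all 5 past when adjusted over the list alone).

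Of 12 hypoxia and glycolysis features, 10 were lower and 2 higher, a split that did not pass (Fisher's exact adjusted p = 0.097, all 12 past when adjusted over the list alone). The glucose transporter Slc2a3 was 2.38-fold lower, and the glycolytic enzyme Pkm and the stress-response gene Ndrg1 were 1.46-fold and 1.44-fold lower. The glycolytic enzymes Ldha and Aldoa were 1.15-fold and 1.13-fold lower as deposited, and turned slightly positive without passing when libraries were scaled to equal ribosomal protein RNA. The vasodilator peptide gene Adm rose 3.11-fold and Hif1a rose 1.44-fold. All 5 features of the respiratory chain list were lower, by 1.23-fold to 1.41-fold, with Atp5g1 and CYC1 at 1.41-fold and 1.37-fold, Atp5a1 at 1.33-fold and Cox5a at 1.30-fold (Fisher's exact adjusted p = 0.097, all 5 past when adjusted over the list alone). Unfolded protein and amino acid stress genes were split, 6 higher and 3 lower (Fisher's exact adjusted p = 0.179, all 9 past when adjusted over the list alone). DDIT3, a stress-induced transcription factor, was 2.07-fold higher, and XBP1, a regulator of secretory capacity, was 1.77-fold higher. Ppp1r15a was 1.62-fold higher, and the serine-synthesis enzyme Psat1 was 1.71-fold lower.

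The list of cytosolic ribosomal proteins, which was partial and also held the elongation factor gene Eef1a1, had 24 of its 25 features lower, by 1.08-fold to 1.39-fold, as deposited (Fisher's exact adjusted p = 6.37e-05, all 25 past when adjusted over the list alone). Of the 38 genes of this list, 23 were in the table. RPS5, Rps27a and Rpl3 were 1.39-fold, 1.37-fold and 1.30-fold lower. The exception was a low copy of Rps20 on chromosome 3, at 15.9 ± 2.19 RPKM in controls and 30.2 ± 10.3 RPKM in knockdowns, while the main Rps20 feature was 1.26-fold lower. By name, the table held 43 cytosolic ribosomal protein features, 19 of them outside the list and all 19 lower, and Rpl10l had the largest fall, 1.55-fold. Scaling to equal RNA of the ribosomal protein list, chosen after the data were seen, shifted the median log2 change of the table by 0.22 and turned 12 of the 25 features, and 17 of the 43, the other way, with an adjusted p of 1.0 for the split, within a range of 9.73e-06 to 1.0 over its alternatives. By construction it removes the median fall of this list, so these turns and the lost split say nothing about the source of the falls. All 27 cell cycle features and all 5 stem-state features stayed lower and past the threshold under that scaling.

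**Figure D3:**
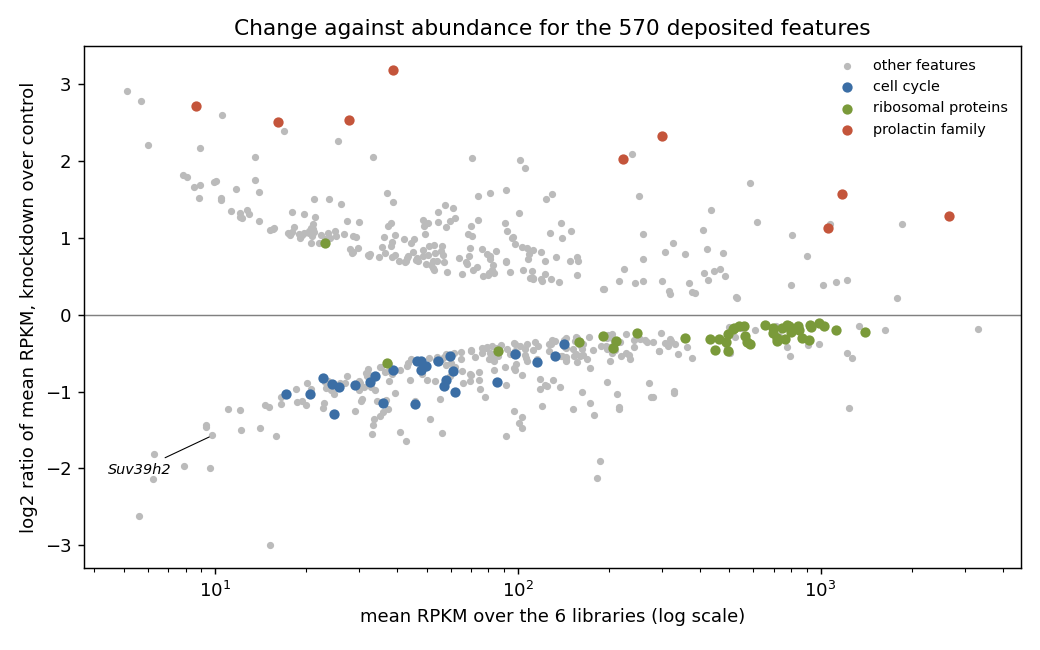
Log2 ratio of mean RPKM, knockdown over control, against mean RPKM over the 6 libraries on a log scale, for the 570 deposited features, with cell cycle, ribosomal protein and prolactin family features in colour. Of the 43 ribosomal protein features by name, 40 were over 100 RPKM in controls, and 42 were lower as deposited, by at most 1.55-fold, of which 17 turned higher under scaling to ribosomal protein RNA, whereas the smallest fold among the 83 features under 20 RPKM in controls was 1.81. That scaling removes the median fall of the ribosomal protein list by construction.

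The largest fall in the table was that of Adipor2, an adiponectin receptor, which was 7.95-fold lower (27 ± 2.15 to 3.4 ± 0.253 RPKM). The metallothioneins Mt1a and Mt2A, small metal-binding proteins, fell 4.38-fold (298 ± 27.5 to 68.1 ± 6.47 RPKM) and 3.73-fold (295 ± 38.2 to 79.1 ± 3.42 RPKM). Their sequences are close, so the division of reads between them is uncertain too. The epithelial surface protein gene Tacstd2 and the tubulin-associated gene Tppp3 were 3.98-fold and 3.92-fold lower. The histone genes Hist3h3, Hist1h2bd and Hist1h2ah were 4.42-fold, 3.13-fold and 2.93-fold lower, and a second copy of Hist1h2ah was 1.72-fold lower. The splicing factor gene Txnl4a was at 11.6, 7.27 and 10.5 RPKM in controls and at 2.08 and 6.29 RPKM and listed at 0 in knockdowns (3.51-fold on the means, adjusted p = 0.0177). Its adjusted p was 0.0514 without control library S4 and 0.0505 with a pseudocount of 0.1, within a range of 0.001 to 0.0514 over its alternatives. Without the knockdown library listed at 0, its log2 change went from -1.91 to -1.16.

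The remaining lists had fewer than 5 features in the table and were not tested. Of the 21 genes of the labyrinth and syncytiotrophoblast list, 2 were in the table, Slc2a3 and the protease inhibitor Spint1, both 2.38-fold lower. Fdps, of cholesterol synthesis, was 1.49-fold lower. The p53 target Gadd45a, a growth-arrest gene, was 3.38-fold higher (6.19 ± 0.827 to 20.9 ± 0.868 RPKM). The class I histocompatibility genes RT1-A2 and RT1-A1, the members of the list of interferon-stimulated genes in the table, were 3.33-fold and 1.67-fold higher. Among markers of other cell types, the leukocyte integrin Itgax, 1 of 22 listed leukocyte genes, was 2.11-fold higher, and outside the list the leukocyte-type genes Itgb2 (the partner of Itgax), Was and Spn were 2.71-fold, 2.15-fold and 1.68-fold higher. The endothelial cadherin Cdh5, which giant cells and invasive trophoblast also express, was 2.13-fold higher. The lists for stroma and decidua and for endoderm and embryo had 0 features in the table. Every feature of these lists passed when adjusted over the list alone.

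The deposit also marks 38 candidates chosen by the study, of which 26 were higher and 12 lower. Their largest rises were Prl3b1, Prl5a1, Prl2a1, Mmp12 and Ceacam9, and their largest falls were Dnmt3l, Mt1a, Suv39h2, Id2 and Id1. Of the 38, 26 were members of at least 1 of the lists above. They were picked on these same samples, so their directions are not independent evidence.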

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

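The ribosomal protein scaling, the 1.5-fold limit and the single feature per gene were chosen after the data were seen. Suv39h2 stayed lower and past the threshold under every alternative that was run, with log2 changes from -1.76 (quantile normalization) to -1.19 (ribosomal protein scaling), and from -1.45 to -1.36 when single libraries were left out. The replicate block gave 242 higher and 328 lower features and a Suv39h2 change of -1.40. After the group mean of each feature was subtracted, correlations between same-numbered control and knockdown libraries were -0.032 to 0.015. Those between differently numbered ones were -0.069 to 0.088, so no effect shared by number was seen in these features. Whether same-numbered libraries were handled together is not stated. Requiring 2-fold left 116 higher and 68 lower features and gave the matrix and adhesion list an adjusted p of 0.328. Of that list 7 features stayed, 6 higher and 1 lower. The share of other features that were higher went from 41.61% to 62.15%, so the comparison changed as well as the number of features. Requiring 1.5-fold left 199 higher and 159 lower features. Under both limits more features were higher than lower, but the higher features also had the lower median abundance in controls. Ribosomal protein scaling moves the ribosomal median to 0 by construction. It left the ribosomal list with 6 higher, 6 lower and 13 features not past, and an adjusted p of 1.0. The scaling ended 41 calls and turned 24 features, 7 of them past the threshold, leaving 249 higher and 280 lower. It gave steroid synthesis 0.0543: its raw p went from 0.0135 to 0.0226 and its rank among the 12 lists from 6 to 5. Quantile normalization ended 21 calls and turned 3 features, none past the threshold. Leaving out single libraries ended at most 2 calls, those of Txnl4a and Rps18. Under a fold of at least 2 or a single feature per gene, steroid synthesis had under 5 features and no test. The low-value filters removed no feature and say nothing. Tests on counts were not run. With depth unknown, counting error cannot be separated from other spread.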

Other observations

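The 5 gene lists and the tests of scaling and of the false discovery rates given here were chosen only after the results were seen. All 41 histone features, from 32 names, were lower, by 1.39-fold to 4.42-fold with a median of 2.03-fold (Fisher's exact adjusted p = 4.72e-10 over these 5 lists), and all stayed lower and past the threshold under both scalings. Of these, 29 lay on chromosome 17 between 45468538 and 58950698, just beyond the prolactin family, whose 9 features all rose. The copies are near identical, so values of single copies are uncertain. Subunits of the CCT chaperonin, which folds actin and tubulin, were lower in 8 of 8 cases, by 1.22-fold (Tcp1) to 1.53-fold (Cct2), with an adjusted p of 0.0295, and all 8 stayed lower under both scalings, though Tcp1 no longer passed under ribosomal protein scaling and Cct7 no longer passed under quantile normalization. The adjusted p of the split under its alternatives ranged from 0.0202 to 0.0519, the latter with features at a deposited false discovery rate of 0.01.

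Cathepsins and lysosomal proteins were higher in 12 of 12 cases (Fisher's exact adjusted p = 7.3e-05, and 0.159 among features of at least 2-fold, in a range of 6.58e-05 to 0.159 over its alternatives). They included the ubiquitous Ctsd (2.12-fold), Ctsb (1.81-fold) and Lgmn (1.75-fold) besides the placental Ctsq and Ctsj. Actin cytoskeleton and focal adhesion genes were higher in 18 of 22 cases (adjusted p = 0.000359), with the actin-binding peptide gene Tmsb4x at 4.02-fold, moesin (Msn) at 2.35-fold and zyxin (Zyx) at 1.86-fold. Actb was 1.16-fold higher as deposited and turned lower without passing under quantile normalization, under which Tpm4 stayed higher but no longer passed. Epithelial junction genes were lower in 13 of 16 cases, a split that did not pass as deposited (adjusted p = 0.0707) but passed under quantile normalization (0.0438) and ribosomal protein scaling (0.0228), in a range of 0.0228 to 0.0946 over its alternatives. Cgn and Epcam were 2.35-fold and 1.71-fold lower, and Cgnl1, PKP2 and Jup were 2.03-fold, 1.81-fold and 1.67-fold higher.

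Falls across many lower features could come from scaling to library totals, if a few transcripts took more of the reads in knockdown cells, and such a factor moves every feature alike. The median log2 change of the 32 cell cycle and stem-state features differed by -0.571 from that of the 42 ribosomal protein features that fell. The size of this gap may partly reflect selection. The smallest fold in the table was 1.81 under 20 RPKM in controls and 1.08 over 500 RPKM, where 33 of the 42 lay. Of the 32, 96.9% lay over 3 standard errors from the ribosomal median. All 32 stayed lower and past the threshold after ribosomal protein scaling. Selection favours both results. That scaling shifted log2 changes by 0.22, less than the falls of these features, which were at least 1.30-fold. Their survival of it therefore adds no evidence. For these listed features, a distance from the ribosomal median beyond their spread between libraries argues against scaling as the whole source of their fall. Members absent from the table cannot be judged. Among those 42, 13 (31.0%, exact 95% interval 17.6% to 47.1%) lay over 3 standard errors from their median. So did 7 of the 33 over 500 RPKM (21.2%, 8.98% to 38.9%), where chance gives 1.85% in both cases. The intervals treat features as independent, which features of the same 6 libraries are not. The standard errors hold only the spread between these libraries. The sizes of the falls differed beyond that spread, which argues against a common factor alone without settling it. The comparison with chance was chosen after an earlier bound of 20%, which lies inside the first interval and would have left this undecided. The common part of the ribosomal falls, a median log2 change of -0.242, cannot be told apart from such a factor. No unselected feature is in the table to compare it with, and the median covers only features that passed selection and fell. Of the 38 genes of the ribosomal protein list, 23 were in the table. Whether the absent genes fell by as much is unknown. The reduced Suv39h2 level stays open as an untested biological source.

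The order of the deposited false discovery rates may come from RPKM values having been treated as read counts. Across the 570 features, which are not independent replicates, the rates had a Spearman rho of 0.954 with a test of the summed RPKM taken as counts. The rho was 0.449 with the limma p, which weighs each change against the spread between replicates. The smallest fold was 1.81 among 83 features under 20 RPKM in controls and 1.08 among 65 features over 500 RPKM. On this reading, changes under about that size in features of low abundance would be missing from the table whatever their spread. The authors' test is not stated, other tests were not tried, and no biological explanation was tested.

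Neighbouring features tended to change in the same direction: 65.8% of 237 pairs within 1000000 bases, against 44.7% to 57.4% with directions permuted (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Without pairs of the same gene family, 54.6% of 174 pairs did, within the permuted range of 43.7% to 58.6% (one-sided permutation p = 0.2). Clusters of gene families, such as prolactins and histones, could therefore account for the pattern. A smaller effect of chromatin domains is not excluded, and no biological explanation was tested.

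Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many features past the threshold as the real one, the real one itself (570, against 0 in the highest other split). With 10 splits, no share under 0.05 can be reached, and the features had been selected on the real split, which favours it.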
